A study of Mus musculus with 12 samples.

How the data were processed

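RNA was measured in 12 libraries of mouse embryonic fibroblasts, which are connective tissue cells grown from embryos, in 4 genotype groups of 3. Per the labels, the cells came from male E15.5 embryos of C57BL/6N stock in which mice lacking Ing1 and mice lacking Gadd45a were interbred, and were grown for 4 passages and harvested at 80% confluency. Polyadenylated RNA was made into libraries with a kit that does not mark strand and read for 51 cycles from 1 end, per the labels' protocols. The labels do not say whether the 3 libraries of a group came from separate embryos or from cultures of the same embryo, so the p-values below measure the spread between libraries.

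The values used are the counts per gene that the authors deposited, 1 table per library. Per the submitters' processing notes, reads were mapped with TopHat2 2.0.9 and Bowtie2 2.1.0 to mm9 (NCBIM37), counted per gene with HTSeq 0.5.4 and compared with DESeq. The strand setting of the counting is not given in the sources used here. With a kit that does not mark strand, a gene and a gene that overlaps it on the other strand cannot be told apart, and such genes are named as overlapping where they are given. Counts of genes with near-identical copies are uncertain too, because reads that map to several places were counted to no gene. This applies to the Oas, Ifit, Gbp and Slfn families, to histone genes and to ribosomal protein genes, which have many pseudogene copies.

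Each table held 37991 gene identifiers and 5 summary lines. The summary lines were left out of every library total. A share of 23.89% to 24.91% of the reads listed per library was assigned to no gene, most of it reads that did not map to a unique place (17.9% to 19.12%). Gene counts per library ran from 31493168 to 42852059, and the 10 most abundant genes held 10.15% to 11.88% of them. No 2 libraries had the same counts, and replicates of a group differed by 5.27 to 31.26 times counting noise (chi-square per degree of freedom, genes with at least 10 counts). Symbols, chromosomes and gene order came from a GENCODE annotation of another genome build than the authors used, so no coordinates are given; 32938 identifiers had a symbol, and 13321 had a count of 0 in every library.

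Differences between groups were tested with edgeR 4.0.16 in R 4.3.3, in a single model of the 12 libraries with 4 groups, TMM normalisation, a filter on low counts (filterByExpr, which left 15098 genes), robust quasi-likelihood dispersions and two-sided tests. A gene is called when its Benjamini-Hochberg adjusted p within a comparison is under 0.05. The biological coefficient of variation was 8.2%, with 8 residual degrees of freedom. Levels are CPM, the usual unit of counts divided by the TMM-scaled library size, log2 fold changes are edgeR's with their standard error (SE), and list levels are means of log2 CPM with a prior count of 2. DESeq2 1.42.0 was run beside edgeR. The interaction is the log2 fold change of the group labelled double knockout against the WT, less the log2 fold changes of both single knockout groups against the WT. An exact permutation test of 3 libraries against 3 cannot give a two-sided p under 0.1, so no such test was run on single values.

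The comparisons, the tests, the rule for naming genes and 29 gene lists were fixed before the data were examined. Of 634 list members, 624 had a gene identifier. A list was tested where at least 5 members passed the filter, which left out the list of germline genes silenced by methylation, with 4. Lists were tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera asks whether the genes of a list moved more than the other genes did. It was run again with a correlation estimated from the libraries. Fry, in the same package, asks whether the genes of a list moved on balance in 1 direction, and compares them with no other genes. Members called were counted over all genes tested and adjusted over the list alone.

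Genes are named by this rule. In comparisons with the WT they are Ing1, Gadd45a and the 8 genes that rose most and the 8 that fell most among called genes with a mean of 2 CPM or more, a symbol and no overlap between the libraries of both groups. In the other comparisons they are the 4 that rose most and the 4 that fell most, without the condition on overlap for the interaction. From each list and comparison up to 3 called members with the smallest adjusted p are named, or up to 2 abundant members where none was called. Genes called in all 3 comparisons with the WT in 1 direction were to be named too, and there were none. Xist and 4 genes of the Y chromosome check the sex. Results on some genes that were examined are not reported here. A gene named outside this rule is said to have been chosen after its values were seen.

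The test was tried on simulated counts drawn from the means and sizes of the real libraries, with 200 of 15098 genes changed. In the comparison of the labelled double knockout with the WT, edgeR recovered 42% of the genes changed 1.25-fold, 66% of those changed 1.5-fold, 78% at 2-fold and 96% at 4-fold, and 3.4% of its calls were false. In the comparison of the labelled Gadd45a knockout with the WT it recovered 26%, 60%, 78% and 96% at the same fold sizes, with 5.1% false. For the interaction it recovered 8%, 48%, 70% and 96%, with 7.5% false. DESeq2 made more false calls on the same simulated counts: 9.9%, 14.3% and 21.1% of its calls in these 3 comparisons.

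Because the comparisons with the WT share 3 WT libraries, their overlap was set beside 20 simulations in which no group differed from the WT. Neighbours of the targeted genes, 100 annotated genes on either side, were compared with all other genes by a two-sided Fisher's exact test. Alternatives tried were another normalisation (RLE), no filter on low counts, dispersions without robust fitting, the replicate number as a block, leaving out each library, DESeq2, fitting only the groups compared, and leaving out the targeted genes with their neighbours. The macrophage level as a covariate, and leaving out Gadd45a knockout replicate 1 from comparisons that do not hold it, were added after the data had been seen.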

Results

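RNA was counted in 12 libraries of mouse embryonic fibroblasts from 4 genotype groups with 3 libraries each: wild type (WT), Ing1 knockout (Ing1 KO), Gadd45a knockout and double knockout (DKO). Ing1 encodes a chromatin protein that reads a histone mark of active promoters, and Gadd45a encodes a stress-induced protein with roles in DNA repair and DNA demethylation. The total of gene counts was 36593702, 37011208 and 33098932 in WT replicates 1 to 3, and 38763431, 41320533 and 41911611 in Ing1 KO. It was 38110261, 39977288 and 42852059 in the libraries labelled Gadd45a knockout, and 35513328, 31493168 and 38070996 in those labelled double knockout.

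Ing1 was low in the libraries labelled as lacking it, while Gadd45a was higher in those labelled as lacking it. Ing1 (ENSMUSG00000045969, chromosome 8) stood at 52.3 ± 2 CPM in the WT and 52.2 ± 2.4 CPM in the libraries labelled Gadd45a knockout. It stood at 1.22 ± 0.2 CPM in Ing1 KO and 1.12 ± 0.19 CPM in those labelled DKO (SD, n = 3 each). Gadd45a (ENSMUSG00000036390, chromosome 6) stood at 21.1 ± 0.2 CPM in the WT and 18.4 ± 1.9 CPM in Ing1 KO. It was higher in the libraries labelled knockout, at 100 ± 22 CPM in those labelled Gadd45a knockout and 126 ± 6.3 CPM in those labelled DKO (SD, n = 3 each). Among the libraries labelled Gadd45a knockout, replicate 1 was lowest at 75.9 CPM, and replicates 2 and 3 had 118 and 106 CPM. The part of Gadd45a that was deleted is not given in the sources used here, and a gene-level count taken outside the deleted part does not check the label. The groups are therefore named as the libraries labelled Gadd45a knockout and labelled DKO, and every direction given for them rests on these labels. The names WT and Ing1 KO rest on the Gadd45a labels as well, since an exchange of these labels was not excluded. Gadd45a overlaps another annotated gene on the opposite strand. The Y chromosome genes Ddx3y, Kdm5d, Eif2s3y and Uty were expressed in every library, as the label male requires.

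**Figure D1:**
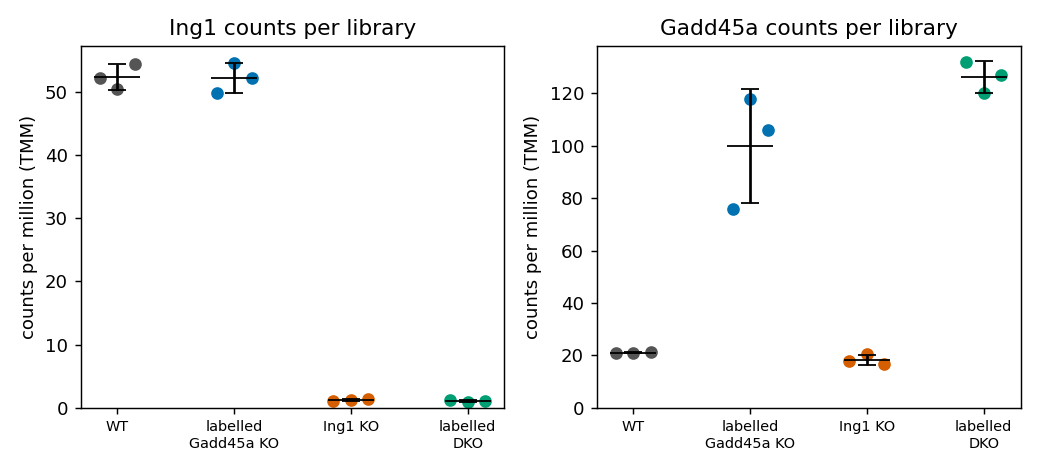
Ing1 and Gadd45a in each library, in CPM (points), with the mean and SD of 3 libraries per group (bars). Ing1 was near 1 CPM in Ing1 KO and labelled DKO, while Gadd45a was higher in the libraries labelled Gadd45a knockout (mean 100) and labelled DKO (mean 126) than in the WT (mean 21.1).

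The libraries labelled DKO stood apart from all others on the main axis of a principal component plot, which held 46.1% of the variance: they lay between 41.7 and 48.9 and the other 9 libraries between -39.7 and 0.7. Ing1 KO lay apart on the next axis (20% of the variance), between -39.8 and -21.3. Between 2687 and 3988 genes were called in each comparison but that of the labelled Gadd45a knockout with the WT, in which a single gene was.

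**Figure D2:**
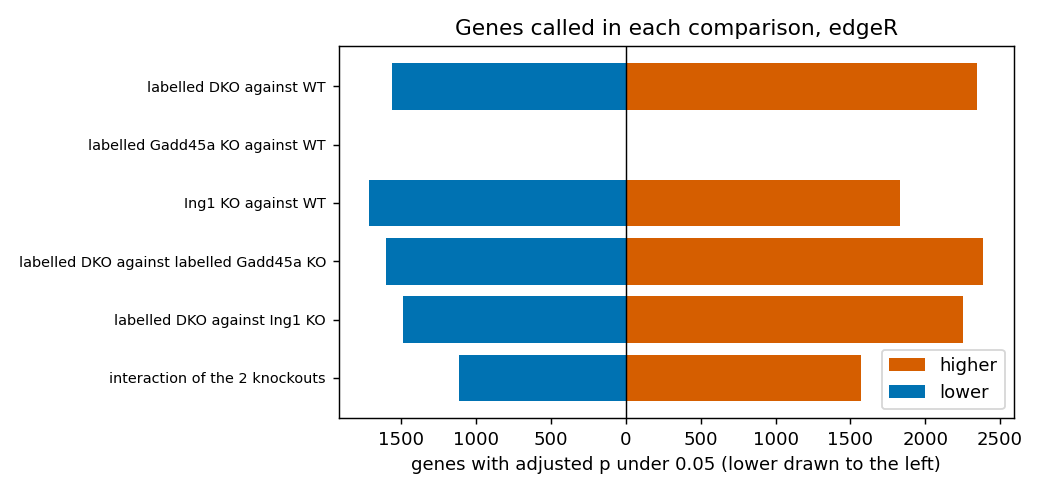
Number of genes called by edgeR at an adjusted p under 0.05 in each of the 6 comparisons, higher to the right and lower to the left of 0. Calls ran from 1 gene in the labelled Gadd45a knockout against the WT to 3988 genes in the labelled DKO against the labelled Gadd45a knockout.

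Loss of Ing1 alone, as labelled, was asked about by comparing Ing1 KO with the WT. Genes that cells switch on in response to interferon fell: Isg15 fell from 18.9 ± 5.6 to 3.8 ± 0.62 CPM and Ifit1 from 8.97 ± 2.5 to 1.53 ± 0.52 CPM (SD, n = 3 each). Slfn5, another gene of this response, fell most after Ing1 itself, with a log2 fold change of -3.04 ± 0.19 (SE, edgeR adjusted p = 1e-05). Oasl2 and Usp18 fell 5.45-fold and 4.84-fold, and Egfl6, which encodes a secreted matrix protein, fell from 103 ± 14 to 18.3 ± 7.1 CPM (SD, n = 3). The genes that rose most included the cartilage genes Acan, Col2a1 and Col10a1 and the limb transcription factor gene Pitx1, which rose 4.02-fold (log2 fold change 2.01 ± 0.32, edgeR adjusted p = 0.00139). Acan reached 13.1 ± 12 CPM and Col2a1 27.6 ± 17 CPM in Ing1 KO, so their level varied widely between the 3 libraries. Col2a1 lost its call without WT replicate 2 (log2 fold change 2.25), WT replicate 3 (2.42), Ing1 KO replicate 1 (2) or Ing1 KO replicate 2 (2.42). Both genes lost the call when only the libraries of these groups were fitted (log2 fold change 3.62 for Acan and 2.48 for Col2a1). Rbfox1, better known from neurons, rose 3.73-fold.

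Of 15098 genes tested, 3543 were called in Ing1 KO against the WT, 1828 higher and 1715 lower, and 144 of the higher and 282 of the lower changed at least 2-fold. The median size of a called change was 0.33 (log2). DESeq2 called 3620 genes. The count rested in part on single libraries: it was 2113 without WT replicate 2 and 1858 without Ing1 KO replicate 2. Slfn5, Col10a1, Smoc1 and Srebf2 overlap another annotated gene.

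The interferon list showed the widest change in Ing1 KO. Of its 25 genes, 22 fell, 3 were not called and none rose, with a median log2 fold change of -1.63 (camera adjusted p = 7.39e-16, adjusted p = 0.341 with an estimated correlation, fry adjusted p = 0.00168). Adjusted over the list alone, 24 fell. Gbp3, which encodes an interferon-induced GTPase, fell 3.33-fold. Leaving out any single library of Ing1 KO or the WT left between 20 and 24 of the 25 called lower.

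Genes for sterol synthesis rose together in Ing1 KO. Of 19, 17 rose and 2 were not called, and adjusted over the list alone 17 rose too, with a median of 0.48 (camera adjusted p = 2.32e-10, adjusted p = 0.341 with an estimated correlation). Srebf2, the regulator of the pathway, rose 1.37-fold. Contractile genes of smooth muscle also rose: 9 of 14 rose and 5 were not called (12 rose adjusted over the list alone), with a median of 0.45 (camera adjusted p = 1.41e-06, adjusted p = 0.341 with an estimated correlation). Cnn1 rose 1.75-fold and Tpm1 1.45-fold. Of 19 immediate early genes, which respond to growth signals within minutes, 11 rose and 8 were not called (12 rose adjusted over the list alone), among them Nr4a1 at 1.44-fold and Egr2 at 1.72-fold. Their median was 0.39 (camera adjusted p = 3.85e-05, adjusted p = 0.341 with an estimated correlation).

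Targets of p53, which halts growth after damage, rose in Ing1 KO more often than they fell: 13 of 24 rose, 2 fell and 9 were not called, the same numbers adjusted over the list alone. The median was 0.28 (camera adjusted p = 0.00485, adjusted p = 0.541 with an estimated correlation), and Pmaip1 rose 1.67-fold and Mdm2 1.22-fold. Imprinted genes fell: 8 of 17 fell and 9 were not called (9 fell and 1 rose adjusted over the list alone), with a median of -0.33 (camera adjusted p = 0.00239, adjusted p = 0.382 with an estimated correlation). Cdkn1c, a growth inhibitor, fell from 138 ± 18 to 63.9 ± 12 CPM (SD, n = 3 each), and Plagl1 fell 2.19-fold. Of 19 genes of the insulin and IGF axis, 7 fell, 1 rose and 11 were not called (7 fell and 3 rose adjusted over the list alone), with Ghr, the growth hormone receptor gene, at 1.41-fold lower. The median of that list was -0.15 (camera adjusted p = 0.0294, adjusted p = 0.341 with an estimated correlation), and the camera adjusted p was 0.0638 without WT replicate 1.

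Genes of energy metabolism moved little in Ing1 KO. Of 12 mitochondrially encoded genes 4 fell and 8 were not called (8 fell adjusted over the list alone), with mt-Co2 at 1.19-fold lower and a median of -0.18 (camera adjusted p = 0.00239, adjusted p = 0.382 with an estimated correlation). Of 32 nuclear genes of oxidative phosphorylation 9 rose and 23 were not called (9 rose adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.00485, adjusted p = 0.412 with an estimated correlation). Of 20 glycolysis and hypoxia genes 5 rose (6 adjusted over the list alone), with Pkm at 0.35 and a list median of 0.19 (camera adjusted p = 0.0103, adjusted p = 0.686 with an estimated correlation). Without Ing1 KO replicate 1 the camera adjusted p of that list was 0.103, and without WT replicate 1 it was 0.093. Of 35 ribosomal protein genes 7 rose (6 adjusted over the list alone), with a median of 0.1 (camera adjusted p = 0.0212, adjusted p = 0.686 with an estimated correlation; 0.206 without WT replicate 3 and 0.13 without Ing1 KO replicate 2).

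The remaining lists that camera called in Ing1 KO stood close to its threshold. Of 32 cell cycle genes 5 rose, among them Plk1, and 27 were not called (5 rose adjusted over the list alone), with a median of 0.05 (camera adjusted p = 0.0487, adjusted p = 0.69 with an estimated correlation). That median was -0.01 without WT replicate 1, and the call was also lost without WT replicate 3 (camera adjusted p = 0.0524) or Ing1 KO replicate 2 (0.18) and with RLE (0.0506). Of 7 epithelial genes 3 rose, the same number adjusted over the list alone, with Krt7 at a log2 fold change of 1.34 (camera adjusted p = 0.0487, adjusted p = 0.341 with an estimated correlation). The epithelial call was lost without WT replicate 1 (camera adjusted p = 0.093), WT replicate 2 (0.145), Ing1 KO replicate 1 (0.0693) or Ing1 KO replicate 2 (0.0585), or with RLE (0.0537) or the replicate block (0.0675). None of 8 replication-dependent histone genes was called by edgeR, and their median was 0.28 (camera adjusted p = 0.0497, adjusted p = 0.382 with an estimated correlation; 0.0654 without WT replicate 2, 0.0764 without Ing1 KO replicate 2 and 0.0537 with RLE).

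Other lists held genes that went both ways in Ing1 KO, and camera called none of them with all 12 libraries. Of 26 fibroblast matrix genes 5 rose and 7 fell (6 and 11 adjusted over the list alone), and Dcn, a collagen-binding proteoglycan gene, fell from 393 ± 43 to 133 ± 33 CPM (SD, n = 3 each). Of 23 adipocyte genes 4 rose, such as Scd1, and 4 fell, such as Cebpa (5 and 4 adjusted over the list alone). Of 22 senescence genes 4 rose, including Cdkn2a at 1.52-fold and Mmp10 at 5.55-fold, and 2 fell, including Igfbp3 at 3.16-fold (5 and 2 adjusted over the list alone). Among 35 Hox genes 6 rose and 2 fell (7 and 2 adjusted over the list alone), and among 27 Gadd45 and ING relatives with the DNA methylation machinery 7 rose and 3 fell, such as Ing3 (9 and 5 adjusted over the list alone). Cartilage had 2 genes higher and 1 lower of 12, osteoblast 3 higher of 8, with Msx2 at 2.12-fold, and brown and beige fat 2 higher and 1 lower of 11. Skeletal muscle had 1 higher and 2 lower of 9, endothelium 1 and 1 of 11, Schwann cell and neuron 1 and 2 of 12, excision repair 3 and 1 of 25, and amino acid and unfolded protein stress 3 and 1 of 22. None of 17 macrophage and blood genes was called, with a median of 0.25. The median, the mean and the camera direction differed in sign for adipocyte, brown and beige fat, endothelium, and the Gadd45 and ING relatives; for brown and beige fat the median was -0.23 and the mean 0.06. Without Ing1 KO replicate 3, camera called cartilage (adjusted p = 0.0134, median 0.69) and osteoblast (adjusted p = 0.0157, median 1.19) higher. Osteoblast was also called without WT replicate 3 (camera adjusted p = 0.0432), and Hox genes without Ing1 KO replicate 2 (camera adjusted p = 0.0406).

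Loss of Gadd45a alone was asked about by comparing the libraries labelled Gadd45a knockout with the WT. The single gene called by edgeR was Gadd45a itself, with a rise of 4.74-fold (log2 fold change 2.24 ± 0.14, SE, edgeR adjusted p = 0.000342). The deleted part is not given in the sources used here, so the label sets no direction for this count. The call of Gadd45a was lost when only the libraries of these groups were fitted, at an unchanged log2 fold change. Ing1 had a log2 fold change of 0 ± 0.07 (edgeR adjusted p = 0.988). At an unadjusted p under 0.05 edgeR had 1331 of 15098 genes. Chance alone puts a share of 0.05 of unchanged genes under that cut. DESeq2 called 28 after adjustment, 12 higher and 16 lower, and 14.3% of its calls were false in simulated counts for this comparison. Without WT replicate 1, edgeR called 13 genes. In simulated libraries of these sizes edgeR recovered 78% of genes changed 2-fold in this comparison, and fewer of those changed less.

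Interferon genes were lower as a group in the libraries labelled Gadd45a knockout than in the WT by camera, and fry did not call them. None of the 25 was called over all genes, all 25 had a negative log2 fold change, and 17 were lower adjusted over the list alone. The median was -0.74 (camera adjusted p = 4.73e-17, adjusted p = 0.494 with an estimated correlation, fry adjusted p = 0.191). All 12 mitochondrially encoded genes also had a negative log2 fold change, none was called over all genes and 10 were lower adjusted over the list alone. Their median was -0.22 (camera adjusted p = 1.11e-13, adjusted p = 0.181 with an estimated correlation, fry adjusted p = 0.0166), and mt-Co1 stood at 2640 ± 100 CPM beside 3060 ± 81 CPM in the WT (SD, n = 3 each).

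The 5 further lists that camera called in the labelled Gadd45a knockout had medians close to 0, and no member of any of them was called over all genes. Sterol synthesis had a median of 0.14 (camera adjusted p = 9.85e-05, adjusted p = 0.755 with an estimated correlation), with 1 of 19 higher adjusted over the list alone and a camera adjusted p of 0.149 without WT replicate 2. Cell cycle had a median of -0.08 (camera adjusted p = 0.00208, adjusted p = 0.817 with an estimated correlation), and lost its call without WT replicate 2 (camera adjusted p = 0.906) or Gadd45a KO replicate 1 (camera adjusted p = 0.129). Ribosomal proteins had a median of 0.05 (camera adjusted p = 0.00208, adjusted p = 0.783 with an estimated correlation; 0.355 without WT replicate 3). Immediate early genes had a median of 0.14 (camera adjusted p = 0.00722, adjusted p = 0.755 with an estimated correlation; 0.196 without WT replicate 2 and 0.401 without Gadd45a KO replicate 2). Amino acid and unfolded protein stress had a median of 0.09 (camera adjusted p = 0.0151, adjusted p = 0.755 with an estimated correlation; 0.149 without WT replicate 2 and 0.178 without Gadd45a KO replicate 3).

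The other lists were not called in the labelled Gadd45a knockout and held no called gene, though 1 imprinted gene was lower adjusted over the list alone. The macrophage list had a median of 0.11, a mean of 0.07 and a camera direction of lower (camera adjusted p = 0.612). It depended on replicate 1, whose macrophage level was 2.22 (mean log2 CPM) beside 3.88 and 3.94 in replicates 2 and 3: without it the median was 0.5 and camera called the list higher (adjusted p = 2.07e-05), and without replicate 3 camera called it lower (adjusted p = 0.0296, median -0.12). Glycolysis and hypoxia genes were called higher by camera without Gadd45a KO replicate 1 (adjusted p = 1.11e-06) or WT replicate 3 (adjusted p = 0.00302), and imprinted genes lower without Gadd45a KO replicate 1 (adjusted p = 0.00243). Signs also differed between the median, the mean or the tests for adipocyte, p53 targets, brown and beige fat, fibroblast matrix, excision repair, oxidative phosphorylation and histone genes.

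The combined loss of both genes was asked about by comparing the libraries labelled DKO with the WT. Genes of macrophages rose most: Arg1 rose from 0.599 ± 0.08 to 7.95 ± 4.4 CPM, Fcgr2b from 1.49 ± 0.59 to 17.3 ± 2.5 CPM and Pf4 from 4.69 ± 1.3 to 39.5 ± 7.6 CPM (SD, n = 3 each). Mrc1, the mannose receptor gene of macrophages, rose 8.04-fold (log2 fold change 3.01 ± 0.53, SE, edgeR adjusted p = 0.00362). Of 17 macrophage and blood genes 16 rose and 1 fell, the same numbers adjusted over the list alone, with a median of 2.38 (camera adjusted p = 2.2e-07, adjusted p = 0.521 with an estimated correlation). The macrophage level was 5.63 to 5.87 (mean log2 CPM) in the 3 libraries labelled DKO and 2.22 to 4.08 in the other 9. It therefore moved with every group of genes below that separates the labelled DKO from the other libraries.

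Genes that fell most in the labelled DKO had fallen in Ing1 KO as well in several cases. Prrg3 fell from 11.2 ± 0.92 to 2.63 ± 0.56 CPM and stood at 3.15 ± 1.1 CPM in Ing1 KO (SD, n = 3 each). Lonrf2 fell 4.23-fold (log2 fold change -2.08 ± 0.16, edgeR adjusted p = 1.93e-05), and Cilp, a cartilage matrix gene, fell 5.95-fold. Aqp1, a water channel gene, fell from 27 ± 6.9 to 5.85 ± 0.85 CPM and stood at 38.5 ± 22 CPM in Ing1 KO (SD, n = 3 each). Ryr3, Mrc1, Aldoa, Ing2 and Irs1 overlap another annotated gene.

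In all, 3909 genes were called in the labelled DKO against the WT, 2348 higher and 1561 lower, with 557 and 310 of them changed at least 2-fold and a median size of 0.42 (log2). DESeq2 called 3886. With the macrophage level as a covariate, chosen after seeing the data, 8 were called: the median size of the 3909 changes became 0.28 and their median SE went from 0.09 to 0.16, while 93.6% kept their sign.

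All 32 cell cycle genes rose in the labelled DKO, over all genes and adjusted over the list alone, with a median of 0.47 (camera adjusted p = 6.78e-16, adjusted p = 0.521 with an estimated correlation, fry adjusted p = 0.00127). Mcm6, which unwinds DNA for replication, rose from 82.8 ± 6.3 to 113 ± 1.4 CPM, and Plk1, a kinase of mitosis, from 22.9 ± 1.4 to 36.3 ± 1.7 CPM (SD, n = 3 each). Glycolysis and hypoxia genes rose too: 18 of 20 rose and 2 were not called, also adjusted over the list alone, with a median of 0.46 (camera adjusted p = 3.46e-08, adjusted p = 0.521 with an estimated correlation). Pkm rose from 1790 ± 30 to 2330 ± 160 CPM (SD, n = 3 each) and Aldoa 1.34-fold. The macrophage level was highest in the same 3 libraries.

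Some Gadd45 and ING relatives with the DNA methylation machinery and some excision repair genes rose in the labelled DKO, while most were not called. Cell cycle genes rose in the same libraries, and whether these rises are linked was not tested. Of 27 Gadd45 and ING relatives with the DNA methylation machinery, 10 rose, 1 fell and 16 were not called (12 and 1 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.00669, adjusted p = 0.374 with an estimated correlation). Uhrf1 and Dnmt1, which copy methylation at replication, rose 1.52-fold and 1.26-fold, and Ing2, the closest relative of Ing1, rose 1.4-fold. Of 25 excision repair genes 9 rose and 16 were not called (9 rose and 1 fell adjusted over the list alone), with Pold1 at 1.36-fold and a median of 0.12 (camera adjusted p = 0.025, adjusted p = 0.521 with an estimated correlation). Of 22 amino acid and unfolded protein stress genes 8 fell, 1 rose and 13 were not called (12 and 1 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.0054, adjusted p = 0.521 with an estimated correlation). Trib3 fell from 87.4 ± 5.6 to 54 ± 5.6 CPM (SD, n = 3 each).

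Several lists had the same sign in the labelled DKO as in Ing1 KO, each against the same WT libraries, so the agreement may come from the shared WT. All 6 had that sign in the labelled Gadd45a knockout too, with medians of 0.07 for contractile, -0.08 for imprinted, 0.14 for sterol, -0.01 for insulin and IGF axis, 0.14 for immediate early and -0.22 for mitochondrially encoded genes. Between the labelled DKO and the labelled Gadd45a knockout, where no WT library is used, contractile genes stood at 8.69 ± 0.18 and 8.42 ± 0.03 (mean log2 CPM, SD, n = 3 each). The insulin and IGF axis stood at 6.47 ± 0.07 and 6.72 ± 0.04. For contractile genes and this axis, that argues against the shared WT as the only reason. The camera call of the axis there was lost without Gadd45a KO replicate 2 (adjusted p = 0.0838). Imprinted genes stood at 6.93 ± 0.15 and 7.16 ± 0.15, immediate early genes at 4.51 ± 0.03 and 4.36 ± 0.16. Sterol genes stood at 5.78 ± 0.07 and 5.73, so the shared WT stays open for these lists. Mitochondrially encoded genes went the other way there (9.25 ± 0.04 and 9.17 ± 0.04). Contractile genes rose in 9 of 14 cases (10 higher and 1 lower adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.00257, adjusted p = 0.521 with an estimated correlation) and Cnn1 at 1.41-fold. Imprinted genes fell in 7 of 17 cases and 1 rose, also adjusted over the list alone, with a median of -0.29 (camera adjusted p = 0.00669, adjusted p = 0.521 with an estimated correlation; 0.0521 without DKO replicate 3), and Ndn and Sgce fell 1.24-fold and 1.34-fold. Sterol genes rose in 6 of 19 cases, also adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.00766, adjusted p = 0.633 with an estimated correlation; 0.106 without WT replicate 2). Of the insulin and IGF axis 5 of 19 fell and 1 rose, also adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.0266, adjusted p = 0.521 with an estimated correlation; 0.0583 without DKO replicate 3), and Irs1, an adaptor of the insulin receptor, fell 1.87-fold. Immediate early genes rose in 8 of 19 cases and 2 fell, such as Klf4 (10 and 2 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.025, adjusted p = 0.526 with an estimated correlation; 0.119 without WT replicate 2). Mitochondrially encoded genes fell in 4 of 12 cases, also adjusted over the list alone, with a median of -0.13 (camera adjusted p = 0.0122, adjusted p = 0.526 with an estimated correlation; 0.0625 without WT replicate 3).

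Small shifts were also called by camera in the labelled DKO. Fibroblast matrix genes had 2 higher and 4 lower of 26 (2 and 5 adjusted over the list alone), with Dcn down 2.4-fold and a median of -0.12 (camera adjusted p = 0.0251, adjusted p = 0.526 with an estimated correlation; 0.108 without DKO replicate 2). Oxidative phosphorylation had 6 of 32 higher (5 adjusted over the list alone) and a median of 0.06 (camera adjusted p = 0.0251, adjusted p = 0.526 with an estimated correlation; 0.0844 without WT replicate 3 and 0.0871 without DKO replicate 2). Ribosomal proteins had 2 higher and 6 lower of 35, also adjusted over the list alone, and a median of -0.08 (camera adjusted p = 0.025, adjusted p = 0.698 with an estimated correlation; 0.244 without WT replicate 1 and 0.0915 without DKO replicate 3).

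The interferon list, which fell in Ing1 KO, was not called in the labelled DKO against the WT: 5 of 25 rose, such as Oas1a and Bst2, 2 fell, such as Gbp2, and 18 were not called, the same adjusted over the list alone (median 0.05, camera adjusted p = 0.701). Also not called by camera were adipocyte genes with 3 higher and 8 lower of 23, p53 targets with 4 and 7 of 24, senescence genes with 5 and 2 of 22, Hox genes with 3 and 2 of 35 and brown and beige fat with 2 and 2 of 11. Endothelial genes had 3 higher and 2 lower of 11: Pecam1 rose to 0.917 ± 0.36 CPM, while Tek fell 4.79-fold to 0.433 ± 0.15 CPM (SD, n = 3 each). Epithelial genes had 2 higher of 7, Schwann cell and neuron genes 2 higher and 1 lower of 12, skeletal muscle 1 and 1 of 9 and cartilage 1 lower of 12. No osteoblast or histone gene was called by edgeR. For cartilage the median was -0.12 and the mean 0.14, and for osteoblast the median was positive and the camera direction lower. Skeletal muscle was called lower by camera without DKO replicate 1 (adjusted p = 0.0463).

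What loss of Ing1 did beside a labelled Gadd45a loss was asked by comparing the labelled DKO with the labelled Gadd45a knockout. Macrophage genes rose here as well, with Arg1 16.5-fold and Ccl6 10.6-fold higher, and 16 of 17 list members rose and 1 fell, also adjusted over the list alone (median 2.32, camera adjusted p = 6.99e-08, adjusted p = 0.499 with an estimated correlation). All 32 cell cycle genes rose, also adjusted over the list alone, with Bub1b at 1.58-fold and a median of 0.56 (camera adjusted p = 4.59e-19, adjusted p = 0.451 with an estimated correlation). Interferon genes rose in 16 of 25 cases and none fell (18 and 1 adjusted over the list alone), with a median of 0.92 (camera adjusted p = 5.74e-06, adjusted p = 0.499 with an estimated correlation). Bst2, which tethers viruses at the cell surface, rose from 22.7 ± 1.9 to 44.3 ± 3 CPM (SD, n = 3 each; log2 fold change 0.97 ± 0.12, edgeR adjusted p = 0.000211). Ryr3 and Lonrf2 fell, as they did in the labelled DKO against the WT, by 5.71-fold and 3.91-fold.

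There were 3988 called genes in that comparison, 2387 higher and 1601 lower, of which 565 and 259 changed at least 2-fold (median size 0.41, log2), and DESeq2 called 3887. Without Gadd45a KO replicate 1, which had the lower Gadd45a count, 2625 of the 3988 were still called, and with the macrophage level as a covariate 3 genes were called: the median size of the 3988 changes went from 0.41 to 0.25 and their median SE from 0.09 to 0.16, while 92.5% kept their sign. Ryr3, P2rx3 and Ccl6 overlap another annotated gene.

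Among the other lists of that comparison, glycolysis and hypoxia rose in 17 of 20 cases, also adjusted over the list alone (median 0.43, camera adjusted p = 5.92e-07, adjusted p = 0.499 with an estimated correlation), and contractile genes in 6 of 14 (6 adjusted over the list alone; median 0.23, camera adjusted p = 0.00815, adjusted p = 0.499 with an estimated correlation). Amino acid and unfolded protein stress genes fell in 12 of 22 cases and 2 rose (15 and 3 adjusted over the list alone), with Trib3 down 1.85-fold and a median of -0.22 (camera adjusted p = 0.000157, adjusted p = 0.499 with an estimated correlation). Ribosomal protein genes fell in 10 of 35 cases (12 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.00012, adjusted p = 0.502 with an estimated correlation). Camera called 6 further lists at an adjusted p between 0.0371 and 0.0495, and each call was lost without at least 1 library. Fibroblast matrix was lower (adjusted p = 0.502 with an estimated correlation; camera adjusted p = 0.149 without Gadd45a KO replicate 2 and 0.099 without DKO replicate 2). Imprinted genes were lower (adjusted p = 0.502 with an estimated correlation; camera adjusted p = 0.176 without Gadd45a KO replicate 1 and 0.128 without DKO replicate 3). Excision repair was higher (adjusted p = 0.499 with an estimated correlation; camera adjusted p = 0.0924 without Gadd45a KO replicate 2 and 0.051 without DKO replicate 1). The insulin and IGF axis was lower (adjusted p = 0.451 with an estimated correlation; camera adjusted p = 0.0838 without Gadd45a KO replicate 2 and 0.0717 without DKO replicate 3). The Gadd45 and ING relatives were higher (adjusted p = 0.451 with an estimated correlation; camera adjusted p = 0.0501 and 0.0934 without Gadd45a KO replicates 1 and 3, 0.0539 without DKO replicate 2, and 0.0601 with the replicate block). Oxidative phosphorylation was higher (adjusted p = 0.534 with an estimated correlation; camera adjusted p = 0.067 and 0.166 without Gadd45a KO replicates 1 and 2, 0.114 and 0.0518 without DKO replicates 2 and 3, 0.0615 with RLE, and 0.0601 with the replicate block). Skeletal muscle was called lower by camera without DKO replicate 1 (adjusted p = 0.0367). Signs differed between median, mean or camera for cartilage, osteoblast, Schwann cell and neuron, Hox and histone genes, none of which was called.

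What the labelled Gadd45a loss did beside loss of Ing1 was asked by comparing the labelled DKO with Ing1 KO. Interferon genes stood out: 23 of 25 rose and 2 were not called (24 rose adjusted over the list alone), with a median of 1.76 (camera adjusted p = 2.29e-15, adjusted p = 0.422 with an estimated correlation). Oas2 and Oas1a, which sense double-stranded RNA, rose 8.98-fold and 7.81-fold, and Bst2 rose from 13.8 ± 0.38 to 44.3 ± 3 CPM (SD, n = 3 each; log2 fold change 1.68 ± 0.12, edgeR adjusted p = 2.33e-05). Macrophage genes rose in 16 of 17 cases and 1 fell, also adjusted over the list alone, with F13a1 15.8-fold higher (median 2.19, camera adjusted p = 3.06e-07, adjusted p = 0.422 with an estimated correlation). Cell cycle genes rose in 28 of 32 cases (30 adjusted over the list alone), with Mcm3 at 1.49-fold and a median of 0.38 (camera adjusted p = 1.27e-12, adjusted p = 0.422 with an estimated correlation). Aqp1 fell 6.54-fold, and Acan, which had risen in Ing1 KO, fell 5.85-fold, a call lost without DKO replicate 1, 2 or 3 (log2 fold change -2.64, -2.57 and -2.45) or with only these groups fitted (-2.57).

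Some lists stood lower in the labelled DKO than in Ing1 KO, and glycolysis and hypoxia genes stood higher. Sterol genes fell in 13 of 19 cases and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 2.11e-05, adjusted p = 0.471 with an estimated correlation). Targets of p53 fell in 13 of 24 cases and 2 rose (15 and 2 adjusted over the list alone), with Plk2 down 1.87-fold and a median of -0.23 (camera adjusted p = 2.58e-05, adjusted p = 0.422 with an estimated correlation). Ribosomal protein genes fell in 15 of 35 cases (21 adjusted over the list alone), with Rpl8 down 1.18-fold and a median of -0.16 (camera adjusted p = 2.55e-06, adjusted p = 0.422 with an estimated correlation). Amino acid and unfolded protein stress genes fell in 13 of 22 cases and 3 rose (14 and 3 adjusted over the list alone; median -0.26, camera adjusted p = 0.000179, adjusted p = 0.422 with an estimated correlation). Glycolysis and hypoxia genes rose in 10 of 20 cases, also adjusted over the list alone, with Ndrg1 at 1.91-fold (median 0.3, camera adjusted p = 0.000407, adjusted p = 0.511 with an estimated correlation). Cdkn2a fell from 55.5 ± 4.6 to 34.6 ± 1.8 CPM (SD, n = 3 each).

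In that comparison 3740 genes were called, 2249 higher and 1491 lower, of which 637 and 243 changed at least 2-fold (median size 0.4, log2), and DESeq2 called 3722. The count was 2249 without Ing1 KO replicate 2 and 18 with the macrophage level as a covariate, where the median size of the 3740 changes went from 0.4 to 0.25 and their median SE from 0.09 to 0.15, while 93.7% kept their sign. Camera also called the Gadd45 and ING relatives higher, with Neil3 at 2.11-fold (adjusted p = 0.0147, adjusted p = 0.422 with an estimated correlation), contractile genes lower (adjusted p = 0.0305, adjusted p = 0.511 with an estimated correlation) and histones lower (adjusted p = 0.0461, adjusted p = 0.422 with an estimated correlation). Contractile genes lost the call without Ing1 KO replicate 2 (camera adjusted p = 0.0702), Ing1 KO replicate 3 (0.0703) or DKO replicate 3 (0.232), and histones without Ing1 KO replicate 2 (0.0702) or with RLE (0.0607). Without Ing1 KO replicate 3, camera also called cartilage (adjusted p = 0.00222) and osteoblast genes (adjusted p = 0.00822) lower. It did so without DKO replicate 1 (0.0293 and 0.0168), and called osteoblast and epithelial genes lower without DKO replicate 3 (0.0405 and 0.0409). Signs differed between median, mean or camera for brown and beige fat, the insulin and IGF axis and oxidative phosphorylation, which were not called. Ndrg1 overlaps another annotated gene.

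Whether the labelled double knockout differs from the sum of the single knockouts was asked by the interaction. Interferon genes departed widely from the sum: their level was 2.28 ± 0.38 (mean log2 CPM) in the WT, 1.66 ± 0.15 in the labelled Gadd45a knockout, 0.87 ± 0.09 in Ing1 KO and 2.48 ± 0.29 in the labelled DKO (SD, n = 3 each). Of 25 genes 24 had a called positive interaction, also adjusted over the list alone, with a median of 2.65 (camera adjusted p = 3.69e-19, adjusted p = 0.449 with an estimated correlation, fry adjusted p = 0.00128). The macrophage level departed about as far, at 3.45 ± 0.41, 3.34 ± 0.98, 3.58 ± 0.44 and 5.71 ± 0.14 in the same order (SD, n = 3 each). Among called genes with a mean of 2 CPM or more, Ccl6 and F13a1, made by macrophages, had the largest positive values at 3.92 and 3.86, followed by Ifit1 at 3.59 and Isg15 at 3.52. The most negative of these genes were Aqp1 at -2.31, Rbfox1 at -2.24, Gata2 at -2.01 and Egflam at -1.94. The F13a1 call was lost without WT replicate 2 or 3 or Ing1 KO replicate 2 or 3 (interaction 3.65 to 3.75), and the Gata2 call without WT replicate 2 or DKO replicate 1 or 2 (-1.94 to -1.89). The Aqp1 call was lost without WT replicate 2 or 3, Gadd45a KO replicate 1 or 2, or any DKO library (-2.39 to -2.18). Ccl6 and Egflam overlap another annotated gene.

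The interaction was called for 2687 genes, 1569 positive and 1118 negative, with 486 and 145 of at least 2-fold (median size 0.46, log2), and DESeq2 called 2968. Without the filter on low counts 1092 were positive and 1168 negative, so which sign was more frequent depended on that filter. The count rested in part on single libraries: it was 1300 without WT replicate 2, 1599 without WT replicate 3, 1386 without Ing1 KO replicate 2 and 1607 without DKO replicate 2. Without Gadd45a KO replicate 1, 1831 of the 2687 were still called. With the macrophage level as a covariate 15 genes were called: the median size of the 2687 changes went from 0.46 to 0.32 and their median SE from 0.11 to 0.16, while 98.1% kept their sign.

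Cell cycle genes had a positive interaction in 23 of 32 cases (27 adjusted over the list alone), with Pcna at 0.5 and a median of 0.49 (camera adjusted p = 3.23e-12, adjusted p = 0.449 with an estimated correlation), and macrophage genes in 8 of 17 (16, and 1 negative, adjusted over the list alone; camera adjusted p = 1.99e-06, adjusted p = 0.449 with an estimated correlation). Sterol genes had a negative interaction in 13 of 19 cases (14 adjusted over the list alone), with Srebf2 at -0.44 and a median of -0.41 (camera adjusted p = 9.71e-07, adjusted p = 0.449 with an estimated correlation). So had amino acid and unfolded protein stress genes in 12 of 22, with Trib3 at -0.76 and a median of -0.38 (14 adjusted over the list alone; camera adjusted p = 9.27e-05, adjusted p = 0.449 with an estimated correlation), and ribosomal protein genes in 11 of 35 (21 adjusted over the list alone; camera adjusted p = 5.24e-07, adjusted p = 0.449 with an estimated correlation). Targets of p53 had 8 negative and 1 positive of 24 (camera adjusted p = 0.00122, adjusted p = 0.449 with an estimated correlation), and mitochondrially encoded genes 5 positive of 12 (camera adjusted p = 0.00116, adjusted p = 0.449 with an estimated correlation). Srebf2 overlaps another annotated gene.

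Other interaction calls rested on single libraries. Immediate early genes, with Egr1 at -0.76, had a negative interaction (camera adjusted p = 0.0251, adjusted p = 0.449 with an estimated correlation; 0.0533 without WT replicate 2 and 0.172 without Gadd45a KO replicate 2). Camera called contractile genes negative as a list, with Cnn1 at -0.42 (camera adjusted p = 0.0237, adjusted p = 0.449 with an estimated correlation; 0.0859 without WT replicate 1 and 0.119 without DKO replicate 3). Few members were called by edgeR: 1 of 14 without WT replicate 1 and 0 without DKO replicate 3. Camera called glycolysis and hypoxia genes positive as a list (camera adjusted p = 0.0479, adjusted p = 0.671 with an estimated correlation). This call was lost without WT replicate 2 (0.0533), WT replicate 3 (0.0941), Gadd45a KO replicate 1 (0.255), Ing1 KO replicate 3 (0.176) or DKO replicate 1 (0.177), or with the replicate block (0.0727). In each of those fits edgeR called at most 1 of the 20 genes. Lists that camera called negative only without a library were cartilage without Ing1 KO replicate 3 (adjusted p = 0.0164) and osteoblast genes without WT replicate 3 (0.0316), Gadd45a KO replicate 1 or 3 (0.0331 and 0.0472), Ing1 KO replicate 3 (0.0164) or DKO replicate 1 (0.03). Hox genes were called so without Ing1 KO replicate 2 (0.0353) or DKO replicate 2 or 3 (0.0273 and 0.0476), and histones without WT replicate 3 (0.0316), Gadd45a KO replicate 1 (0.0204) or DKO replicate 2 (0.0318). Signs differed between median, mean or camera for brown and beige fat, endothelium, fibroblast matrix, the insulin and IGF axis and oxidative phosphorylation, which were not called.

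**Figure D3:**
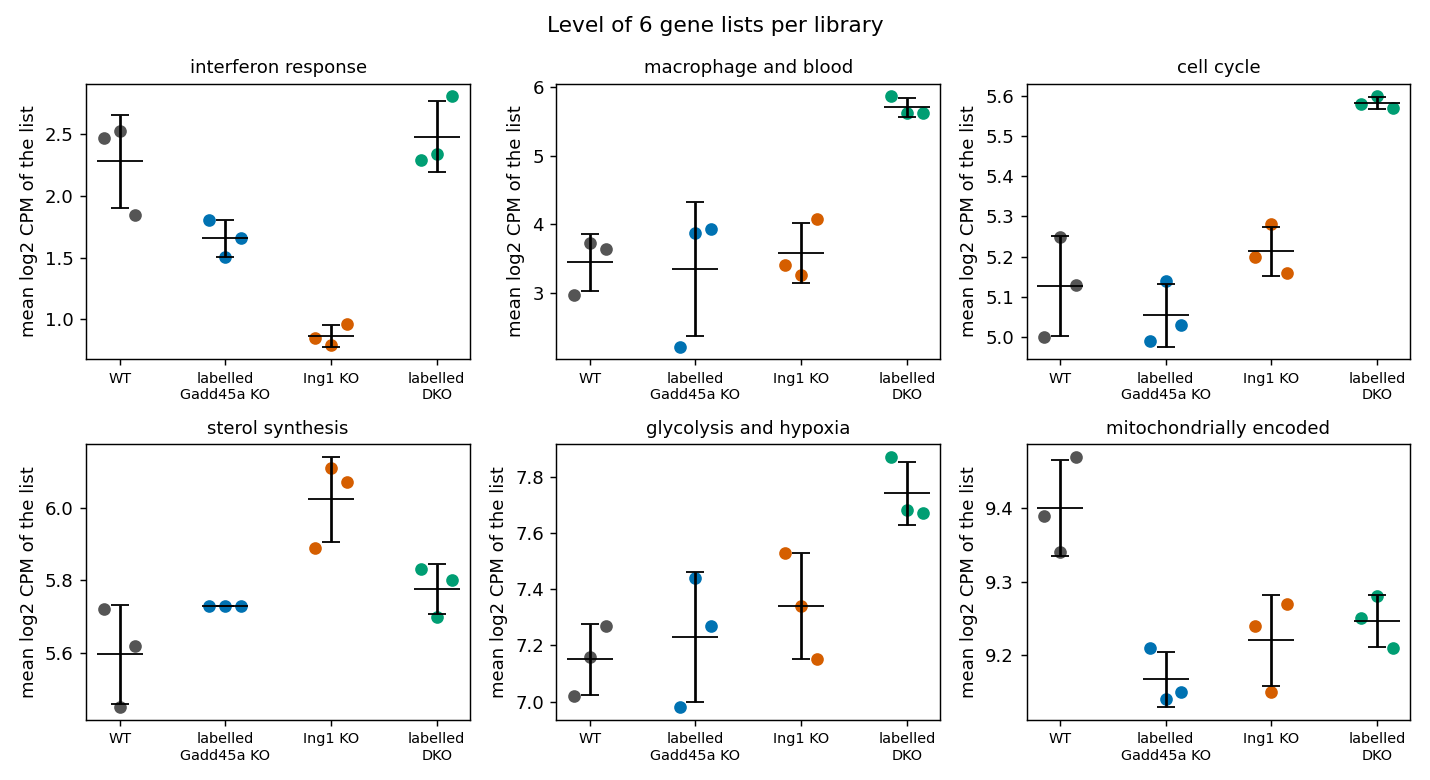
Level of 6 gene lists in each library (points; mean log2 CPM of the list's genes), with the mean and SD of 3 libraries per group (bars). The interferon level was lowest in Ing1 KO (0.87), and the macrophage and cell cycle levels were highest in the labelled DKO (macrophage 5.63 to 5.87).

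Genes called in Ing1 KO and in the labelled DKO, each against the WT, went the same way far more often than chance gives: 724 were higher in both (284 by chance) and 716 lower in both (177 by chance), while 58 went opposite ways (456 by chance). Dcn, lower in both, is an example of the 1440 genes shared. That number was 838 without WT replicate 2 and 958 without Ing1 KO replicate 2. Both comparisons use the same WT libraries. The covariance of the fold changes across genes was 0.095, and 0.022 came from simulated groups that did not differ from the WT. Those simulated groups gave a correlation of 0.503 against 0.418 observed. They held no changed gene, and none was called in both. Their calls therefore cannot show how many of the shared genes the shared WT adds, and no conclusion is drawn from them. Part of the excess may come from the shared controls. Of the 3909 genes called in the labelled DKO, 2410 (61.7%) were called in neither single knockout, and 1225 (31.3%) had a called interaction. Of the Ing1 KO calls, 2045 (57.7%) were called there only.

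The effect of Ing1 loss was also compared between both backgrounds, which share no library. Across 15098 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.282 and a Spearman correlation of 0.254, and 57.2% had the same sign. Of genes called in both, 463 were higher, 510 lower and 191 opposite (289, 182 and 465 by chance). Of 25 interferon genes, 22 were called lower in Ing1 KO against the WT and 16 were called higher in the labelled DKO against the labelled Gadd45a knockout. For the labelled Gadd45a loss the Pearson correlation between backgrounds was -0.025 and the Spearman correlation -0.162, and 40.3% of genes had the same sign; leaving out 1 library moved the Pearson correlation between -0.159 and 0.177.

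**Figure D4:**
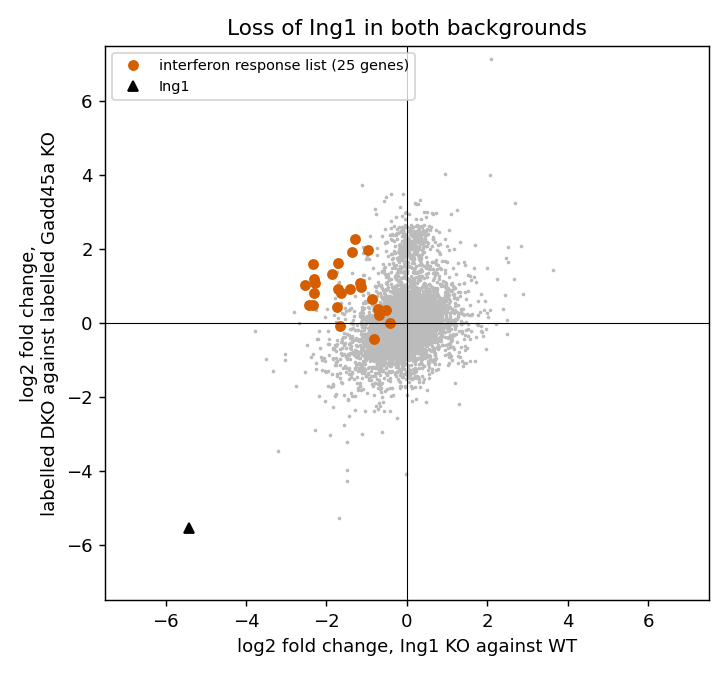
Log2 fold change of each of 15098 genes in Ing1 KO against the WT (horizontal) and in the labelled DKO against the labelled Gadd45a knockout (vertical). Interferon genes (orange, 25 genes) were lower on the horizontal axis (median -1.63) and mostly higher on the vertical axis (median 0.92), while Ing1 (triangle) fell in both.

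Genes near Gadd45a on chromosome 6 were called more often than others in the labelled DKO against the WT. Among the neighbours 23 of 46 tested were called (50% against 25.8% of other genes, odds ratio 2.87, two-sided Fisher's exact test p = 0.000529, adjusted p = 0.00317 over 6 tests). With 200 genes on either side the odds ratio was 1.39 (Fisher's exact test p = 0.0518). The 23 include E230016M11Rik, which overlaps Gadd45a and was chosen after its values were seen. Between the labelled DKO and the labelled Gadd45a knockout, which carry the same Gadd45a label, 16 of the 46 were called (34.8% against 26.4% of other genes). All 16 were among the 23, so linkage to the Gadd45a allele gives no reason for their difference there. Neighbours of Ing1 on chromosome 8 were called in 14 of 71 cases in Ing1 KO (odds ratio 0.8, Fisher's exact test p = 0.574). Neighbours of Ing1 in the labelled DKO against the WT (odds ratio 0.972) and of Gadd45a in Ing1 KO (odds ratio 1.03) each had a Fisher's exact test p of 1. In the labelled Gadd45a knockout against the WT no other gene was called, so the test could show no excess there. In the 3 comparisons that are not with the WT alone, the odds ratios were 1.19 to 1.49 for neighbours of either gene (Fisher's exact test p from 0.177 to 0.493, not adjusted).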

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

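Tests chosen only after their result had been seen were the comparison of other cell types, both tests that predict a list's level from the macrophage level, and the tests on Gadd45a. The other tests were set beforehand.

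The difference between libraries labelled with and without loss of Ing1 depended on the labelled Gadd45a loss, by a test of the interaction: 2687 genes had a called interaction. That count was 1300 without WT replicate 2 and 15 with the macrophage level as a covariate, which largely coincides with the labelled DKO. In that fit the median size of the 2687 changes went from 0.46 to 0.32 and their median SE from 0.11 to 0.16, while 98.1% kept their sign. Calls were lost through smaller changes and larger SE, and RNA of macrophages stays open for this count. As large a count came from 1 of 41 splits of the libraries, the real split, and the highest of the others called 362 genes. The other splits mix libraries of all 4 groups, which differ, and so raise the spread within groups. They therefore cannot tell an interaction from differences between groups that add up, and no conclusion is drawn from them. For the 5 comparisons of group pairs, 3 libraries against 3 give 10 splits, too few for a share as small as 1 of 41. Their real counts were 3909, 1, 3543, 3988 and 3740, each reached by 1 split, and the highest of the other splits called 1, 0, 0, 0 and 1 genes in the same order.

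Genes of macrophages were higher in the 3 libraries labelled DKO, and so the interaction was largest for Ccl6 (3.92) and F13a1 (3.86), while cell cycle genes had a median interaction of 0.49. A smaller share of fibroblasts might raise every other cell type alike. The highest median of 4 lists of other cell types was 0.25 (endothelium), and Schwann cell and skeletal muscle genes stood at -0.31, beside 2.38 for macrophages. In the WT the levels (mean log2 CPM) were low for endothelium (0.52), epithelium (0.11), skeletal muscle (-0.12) and Schwann cell and neuron (1.31), beside 3.45 for macrophages. The low medians argue against a smaller share only if those cell types were present, which was not tested. Macrophages among the cells may be the source, and the labels name no sort that would remove them: of a further list of 19 macrophage genes, written before it was tested, 19 rose, with a median of 2.28 ± 0.05 (bootstrap SE). The mark set beforehand was 2.29, the lower quartile of the main list, so by that rule RNA of macrophages and a change inside the cells cannot be told apart; Mpeg1 and Lcp1, abundant genes of the further list, were chosen after their values were seen and went from 57.6 to 288 CPM and from 59.1 to 240 CPM. Whether RNA of macrophages could raise the cell cycle list stays open too, because the rise it predicts, 0.209 ± 0.286 (jackknife SE, as a multiple of the WT level), spans both 0 and the observed 0.374. Genotype, as labelled, remains an untested biological explanation for both.

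Interferon genes were lower in Ing1 KO than in the WT and in the labelled DKO, with a median interaction of 2.65, and Ifit1 (3.59) and Isg15 (3.52) among the largest. A single library does not carry the fall from the WT: whichever library was left out, at least 20 of 25 genes were still called lower. RNA of macrophages in the labelled DKO is argued against as the reason for the higher level there, since the other 9 libraries predict a change of -0.282 ± 0.379 (jackknife SE, as a multiple of the WT level) and 0.86 was observed. That prediction reaches beyond its range, as the macrophage level was 4.74 to 17 CPM in those 9 libraries and 50 to 59.1 CPM in the labelled DKO. It also takes macrophages to carry the same interferon RNA in every group, which was not measured, so RNA of macrophages is not excluded. An effect of genotype on this response is a candidate explanation that was not tested, and so is a difference between cultures in exposure to interferon, for which the labels give no measure.

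Gadd45a counts were higher in the 6 libraries labelled Gadd45a knockout or DKO than in the other 6. Depth is argued against, because the lowest count of the labelled libraries was 3.42 times the highest of the others, while the deepest library had 1.36 times the counts of the shallowest. An exchange of labels cannot be told apart from a targeted allele that leaves a transcript, because the deleted part is not given in the sources used here: E230016M11Rik, which overlaps Gadd45a and was chosen after its values were seen, had at most 3 counts in the labelled libraries and 7 to 22 in the others. The lower Gadd45a count of Gadd45a KO replicate 1 might come from a mixture with RNA that has the other allele (39.8% by that count), and this stays open as well. E230016M11Rik in that library lay -1.48 SD from the level of the mixture and 1.44 SD from that of an unmixed library, so its few counts do not decide; genotype itself was not tested as a reason.

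Other results differed between the backgrounds by the test of the interaction. Genes of amino acid and unfolded protein stress had a median of -0.38 and sterol synthesis genes of -0.41, and camera called neither list with an estimated correlation (adjusted p = 0.449 for each). Aqp1 (-2.31), Rbfox1 (-2.24), Gata2 (-2.01) and Egflam (-1.94) had the most negative values among called genes with a mean of 2 CPM or more.

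Reads assigned to no gene, which no comparison uses, were slightly more frequent in some groups than in every WT library. Their lowest share was 24.24% in the libraries labelled Gadd45a knockout and 24.39% in Ing1 KO, beside a highest WT share of 24.23%. Reads without a unique place made up at least 18.35% in Ing1 KO and at most 18.18% in the WT.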

How the results depend on the processing

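The macrophage level as a covariate, and leaving out Gadd45a KO replicate 1 from comparisons that do not hold it, were chosen after seeing the data; the other alternatives were set beforehand. Counts of called genes stayed within 1.5 times the reported value, for every comparison but labelled Gadd45a knockout against the WT, under another normalisation, without the filter on low counts, without robust dispersions, with DESeq2, with only the compared groups (not run for the interaction) and without the targeted genes and their neighbours. Labelled Gadd45a knockout against the WT gave 28 genes with DESeq2 (edgeR had 1331 at an unadjusted p under 0.05), 0 with only the groups compared, where Gadd45a itself lost its call at an unchanged log2 fold change of 2.24 (adjusted p = 0.0865), and 0 without the targeted genes and their neighbours, which removes Gadd45a. Fitting the macrophage level left 8 genes for the labelled DKO against the WT, 3 against the labelled Gadd45a knockout, 18 against Ing1 KO and 15 for the interaction. Called changes also became smaller and less certain there: in the labelled DKO against the WT the median size went from 0.42 to 0.28 and the median SE from 0.09 to 0.16. The macrophage level and this group largely coincide, which enlarges the SE, and the reason for the smaller size was not tested. Normalisation with RLE moved the median of all genes by less than 0.02 and the share of called genes that were higher from 60.134% to 54.627% at most (labelled DKO against Ing1 KO).

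Leaving out 1 library of the groups compared gave 2754 to 3536 genes for the labelled DKO against the WT and 2679 to 3404 against the labelled Gadd45a knockout. It gave 2249 to 3676 genes against Ing1 KO, lowest without Ing1 KO replicate 2. Ing1 KO against the WT gave 1858 to 3548, with 1858 without Ing1 KO replicate 2 and 2113 without WT replicate 2. Without Gadd45a KO replicate 1, which these do not hold, the labelled DKO gave 3900 against the WT and 3736 against Ing1 KO, and Ing1 KO against the WT gave 3550. The interaction gave 1300 to 3285, with 1300, 1599, 1386 and 1607 without WT replicate 2, WT replicate 3, Ing1 KO replicate 2 and DKO replicate 2. Labelled Gadd45a knockout against the WT gave 1 to 13 genes, 13 without WT replicate 1. The genes shared by Ing1 KO and the labelled DKO numbered 838 to 1475, with 838 without WT replicate 2 and 958 without Ing1 KO replicate 2. The cause of these differences was not tested. The macrophage list changed direction in labelled Gadd45a knockout against the WT, between -0.13 and 0.5, and was called higher without Gadd45a KO replicate 1. The excess of called genes near Gadd45a was an odds ratio of 1.39 with 200 genes on either side; the cause was not tested.

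Of 71 list results called by camera, all 71 lost the call with an estimated correlation, 5 with RLE, 4 with the replicate block and 30 on leaving out some library, and fry, which asks another question, did not call 17. Of the list results not called, 12 were called by fry, 1 gained a call with the replicate block and 15 on leaving out some library. Of 429 called results for named genes, none was lost with RLE, 15 without the filter on low counts, 1 without robust dispersions, 6 with DESeq2, 15 with the replicate block, 25 of 357 with only the groups compared and 87 on leaving out some library; none reversed. Over all groups the replicate numbers gave little sign of pairing: 4 of 18 pairs with the same number had a correlation above 0.1 and 5 of 12 libraries were closest to their own number. The WT and the labelled Gadd45a knockout held 3 of those 4 pairs (0.34, 0.11 and 0.13). Replicates 2 and 3 of these groups were no closer to their own number. WT replicate 2 had 0.11 with Gadd45a KO replicate 3, and WT replicate 3 had 0.13 with Gadd45a KO replicate 2. Only the pair of replicates 1 stood out, and a pairing of these 2 groups is not excluded. With the number as a block, 3824, 1, 3434, 3856, 3589 and 2514 genes were called in the 6 comparisons in the order of the plot of called genes. The 4 list calls lost with that block were epithelium in Ing1 KO against the WT (camera adjusted p = 0.0675), the Gadd45 and ING relatives and oxidative phosphorylation in the labelled DKO against the labelled Gadd45a knockout (0.0601 each), and glycolysis and hypoxia for the interaction (0.0727). The call gained was cartilage in the labelled DKO against Ing1 KO (0.0322). Depth and spread limit small changes: in simulated libraries for labelled Gadd45a knockout against the WT, edgeR recovered 60% of 1.5-fold and 78% of 2-fold changes.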

Other observations

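Genes of fat, skeletal muscle and bone were on the lists because fibroblasts can take on these fates, and some of these and other single genes had a called interaction (edgeR adjusted p under 0.05). Plin4, a gene of lipid droplets that overlaps another annotated gene, stood at 1.1 ± 0.15 CPM in Ing1 KO and 0.242 ± 0.038 CPM in the labelled DKO, beside 0.5 ± 0.09 CPM in the WT (SD, n = 3 each). Msx2, a transcription factor gene of bone and limb, stood at 2.32 ± 0.33 CPM in Ing1 KO and 0.85 ± 0.23 CPM in the labelled DKO, beside 1.09 ± 0.11 CPM in the WT (SD, n = 3 each). Vim, the main intermediate filament gene of fibroblasts, stood at 3180 ± 140 CPM in Ing1 KO and 2420 ± 110 CPM in the labelled DKO, beside 2480 ± 150 CPM in the WT (SD, n = 3 each). Neil3, a glycosylase gene of base excision repair, stood at 7.32 ± 0.4 CPM in the labelled DKO and 3.47 ± 0.38 CPM in Ing1 KO, beside 4.38 ± 0.68 CPM in the WT (SD, n = 3 each).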
